A study of Mus musculus with 9 samples.

How the data were processed

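Islets were released with collagenase, picked by hand, cultured overnight in RPMI medium and frozen before RNA extraction with DNase treatment, per the labels' protocols. Libraries were made with a stranded total RNA kit for low input and sequenced on a HiSeq2500, per the labels' protocols. The kit keeps strand, but whether the counting used it is not given in the sources used here, so overlapping and antisense genes are uncertain. Total RNA libraries hold ribosomal RNA, and the ribosomal RNA precursor was kept among the genes in the main fit.

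The authors deposited a table of read counts per gene symbol (24420 genes) and a table of FPKM values (24347 genes), with 1 column per library in each. The counts are whole numbers whose totals differ between libraries, so they were taken as raw counts. The FPKM values are the authors' own, per the file headers in the layout of Cufflinks output, and how the libraries were scaled to each other is not given in the sources used here. The tools FastQC, Bowtie2 2.2.4.0, Cuffdiff 2.2.1 and edgeR and the build mm10 are named, with no role or order, per the submitters' processing notes. Which tool counted the reads, and how reads that match several places were treated, is not given in the sources used here. A gene with related copies can therefore lose or share reads, which affects paralogs, pseudogenes and ribosomal protein genes. Among the counted genes, 27 symbols had been turned into dates by spreadsheet software. They held between 0.133% and 0.186% of the counts of a library and were left out, since several genes can give the same date. A further 1406 genes had 0 counts in all libraries.

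Samples were grouped by the genotype in the labels (5 WT, 4 KO) and by sequencing run (3 WT and 2 KO in run 1, 2 WT and 2 KO in run 3). Replicates of a group were compared by a chi-square test of their counts over genes, which gave between 4.11 and 72.9 per degree of freedom, so no pair agreed within counting noise as a library deposited more than once would. Each was counted as 1 sample, as the labels list them. Every sample column of both tables matched a label. Total counts of 3796043 to 6073537 per library limit the precision for genes at a few CPM, and libraries of run 3 were the deeper ones.

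The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM normalization, the default filter on low counts by genotype group and a model of run and genotype. It tested 12501 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and rises and falls are named only for called genes. Adjusted p-values of genes are from this test unless another tool is named. Standard errors were derived from the log2 fold change and its F statistic. CPM values use the TMM-scaled library sizes, and the log2 CPM values of list means were computed with a prior count of 2. The same test was run within each run with the same genes, for the interaction of genotype and run, for the run term, and between f/+ and f/f controls in a model of 3 genotype groups and run.

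Gene lists for islet cell types and pathways were fixed before the data were examined, and 33 of them had at least 3 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 33 lists, and with fry. With the estimated correlation 0 lists were called, against 6 with the preset correlation. fry, which tests each list against no change, called 10 lists in a direction and 26 for change in either direction. Those called lower were the ER, integrated stress response, O-GlcNAc (which holds Ogt itself), insulin and Akt, and lactogen lists. Those called higher were the delta and PP, fibroblast, Schwann, fatty acid synthesis and immediate-early lists. Some genes stand in more than 1 list, and acinar and endocrine cells both express the ER and stress genes.

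The genes named in the text were chosen by a rule written before the data were examined. It takes Ogt, Mgea5, the islet hormone genes Ins1, Ins2, Gcg, Sst and Ppy, and Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3, Iapp, Atp2a2, Hspa5 and Ddit3 in every case. Some genes that the rule takes are not reported here. It adds the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 2 and with all KO libraries on the same side of all WT libraries within each run, which 976 rises and 921 falls met. From each list it takes up to 4 called members with the lowest p, or up to 2 members where none was called. From each other comparison it takes the 3 rises and the 3 falls with the lowest p, and predicted genes are passed over. Genes outside this rule are said to be chosen after their values were seen.

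Alternatives were the model without the run term, DESeq2 1.42.0, limma-voom with and without sample quality weights, RLE size factors, no filter or a filter of at least 1 CPM in at least 4 libraries, the f/f controls alone, each library left out in turn, acinar markers removed or used as a covariate, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1 or without that filter. A pseudocount on FPKM understates the change of low genes. Other alternatives were added after the data were seen. They removed the ribosomal RNA precursor Rn45s and the gene Lars2, left out WT replicates 2 and 5, or left out KO replicate 2 and WT replicate 2. Gene coordinates were taken from the GENCODE M21 annotation of GRCm38, the assembly behind mm10, which placed 12051 of the 12501 tested genes (96.4%).

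Each test was tested on simulated data, drawn for the 12501 genes from the means and library sizes of the real libraries, with 200 genes changed. For KO against WT in all 9 libraries the main test recovered 44.8% of 1.5-fold changes, 67.2% of 2-fold changes and 100% of 4-fold changes, with 8 false calls among 149. Within run 1 it recovered 50.7% of 2-fold changes and within run 3 44.8%. In the test of the run term 59.7% of 2-fold changes were recovered. Of 3 lists shifted by 1.4-fold camera found all 3, with 1 false call. The simulated genes were drawn independently of each other, while the correlation estimated in the real lists reached 0.846 (acinar list). The simulation therefore does not show how camera with the preset correlation performs on correlated lists.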

Results

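RNA was sequenced from pancreatic islets of female mice, the clusters of endocrine cells in which insulin-secreting beta cells are the most abundant type. The 4 knockout (KO) libraries came from mice with floxed Ogt and the Rip-cre transgene, which expresses Cre recombinase from an insulin promoter. The 5 wild-type (WT) libraries came from mice without Cre, of which WT replicates 1 and 3 carried the genotype Ogt f/+ and the other 3 the genotype Ogt f/f. Run 1 held 3 WT and 2 KO libraries, and the later pool, which the labels call both run 3 and the 2nd run and which is named run 3 here, held 2 WT and 2 KO libraries. Total counts lay between 3796043 and 4462754 per library in run 1 and between 5150443 and 6073537 in run 3. At least 1 count was found for 14485 to 15136 genes per library in run 1 and for 20069 to 21067 genes in run 3. The ribosomal RNA precursor Rn45s took 9.62% to 28.5% of the counts, with the highest shares of each run in WT replicate 2 (28.5%) and WT replicate 5 (24.3%). The first principal component held 54.8% of the variance and separated the runs, and the next held 16.5% and separated KO from WT. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

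The main comparison asked how islet RNA differs when Ogt is deleted in beta cells. Ogt encodes O-GlcNAc transferase, which attaches N-acetylglucosamine to serine and threonine residues of nuclear and cytoplasmic proteins, and Mgea5 (also called Oga) encodes O-GlcNAcase, which removes it. Ogt lies on chromosome X from 101640060 to 101684351 on the plus strand (GRCm38, mm10). Ogt stood at 69.6, 54.1, 83.0, 67.0 and 81.8 CPM in WT replicates 1 to 5 and at 23.7, 24.1, 30.9 and 39.3 CPM in KO replicates 1 to 4. Its mean was 71.1 ± 11.9 CPM (SD, n = 5) in WT and 29.5 ± 7.34 CPM (SD, n = 4) in KO, a log2 fold change of −1.30 ± 0.14 (SE) with an adjusted p of 2.44e-05 in edgeR's quasi-likelihood test. The log2 fold change of Ogt was −1.55 within run 1 and −1.08 within run 3. Mgea5, on chromosome 19 from 45750259 to 45783837 on the minus strand, also fell, from 95.9 ± 13.2 CPM (SD, n = 5) to 56.1 ± 8.15 CPM (SD, n = 4). Its log2 fold change was −0.80 ± 0.09 (SE), with an adjusted p of 2.65e-05, and it was −0.84 within run 1 and −0.78 within run 3. For each of the pair, an exact two-sided permutation test of mean log2 CPM within runs gave p = 0.0167, the smallest that the 60 arrangements can give. Of the 14 tested members of the O-GlcNAc cycling and hexosamine list, 2 rose, 3 fell and 9 were not called, with the same 2 rises and 3 falls adjusted over the list alone. The list had a median log2 fold change of −0.20 and was not called by camera (adjusted p = 0.143), but was called without WT replicate 5 (adjusted p = 0.0365). With all libraries fry called it lower (adjusted p = 0.00839). Ogt, the deleted gene, is itself a member of the list and among its 3 falls. Part of the list's fall was therefore set by the deletion, and the list was not tested without Ogt. Gfpt2, a glutamine-fructose-6-phosphate transaminase at the entry of the hexosamine pathway, rose from 1.12 to 3.31 CPM (log2 fold change 1.44, adjusted p = 0.0274). Nagk, the kinase that salvages N-acetylglucosamine, rose by 0.45 on the log2 scale (adjusted p = 0.0338). The call of Gfpt2 was lost without WT replicate 1, KO replicate 1, WT replicate 4 or KO replicate 3 (log2 fold changes of 1.31, 1.22, 1.32 and 1.37). That of Nagk was lost without WT replicates 3 or 4 (0.38 and 0.33) or without any KO replicate (0.48, 0.45, 0.40 and 0.46). The labels do not state which exons of Ogt are floxed, so its remaining counts cannot be divided into intact and deleted transcripts.

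**Figure D1:**
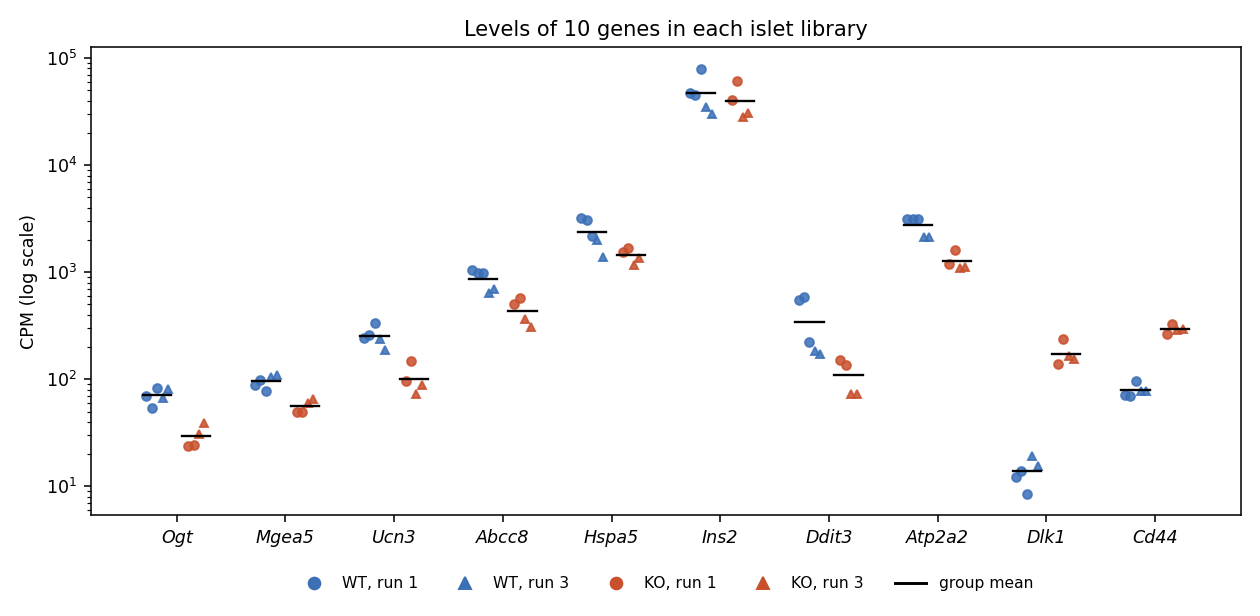
CPM (log scale) of 10 genes in each library, with circles for run 1, triangles for run 3, blue for the 5 WT libraries, red for the 4 KO libraries and black lines for the group means. Ogt lies lower in all 4 KO libraries than in any WT library, and the groups overlap for Ins2.

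The largest rises in KO islets included a ligand of the Notch family, an incretin hormone and a collagen chain, and the largest falls included a gasdermin and a pair of aldo-keto reductases. Dlk1, a membrane-bound ligand of the Notch family, rose from 13.9 ± 4.003 CPM (SD, n = 5) to 174 ± 44.0 CPM (SD, n = 4), a log2 fold change of 3.61 ± 0.19 (SE) with an adjusted p of 1.24e-08 in edgeR's test. Gip, the incretin hormone gastric inhibitory polypeptide, was at 0 CPM in all 3 WT libraries of run 1 and averaged 0.165 CPM in WT and 8.12 CPM in KO. Its fitted log2 fold change of 5.08 depends on the prior count. Chst8, a sulfotransferase of N-acetylgalactosamine, rose by 3.27 on the log2 scale, and Hs6st2, a heparan sulfate 6-O-sulfotransferase, by 2.84. Col8a2, a collagen VIII chain, rose by 3.01, Pcp4, a calmodulin-binding peptide, by 2.94, Meox2, a homeobox transcription factor, by 2.88, and Ak7, an adenylate kinase, by 2.86. The schlafen family members Slfn10-ps (3.52) and Slfn9 (3.23) also rose, but may share reads as related sequences, so their separate values are uncertain. Cd44, the hyaluronan receptor, went from 78.7 to 294 CPM (log2 fold change 1.90), Sema6a, a transmembrane semaphorin, rose by 2.60 and Sumf1, which activates sulfatases, by 1.74. Among the falls, Gsdma, a gasdermin, fell by 1.62 on the log2 scale, Slc25a35, a mitochondrial carrier, fell by 1.58, Tmem97, a sigma receptor, fell by 1.54 and Ciart, a circadian repressor, fell by 1.53. Akr1c12 and Akr1c13, neighbouring aldo-keto reductases on chromosome 13, had log2 fold changes of −1.58 and −1.56, values that are uncertain because paralogs can share reads. Fam129a, a stress-induced regulator of translation, fell by 1.48, and Hfe, a regulator of iron uptake, fell from 76.9 to 27.8 CPM. Adjusted p-values of the genes in these sentences lay between 1.24e-08 (Dlk1) and 0.0096 (Slc25a35).

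In all, 2315 of 12501 tested genes were called at an adjusted p under 0.05, 1195 higher and 1120 lower in KO, and 242 of the rises and 93 of the falls were at least 2-fold. In 2001 of the 2315, every KO library lay on the same side of every WT library within each run, a share that the selection by the same test raises. Over all tested genes that share was 22.9%, against the 3.33% that chance gives on average. The spread of that share over other arrangements of the labels was not computed. DESeq2 called 2197 genes, 2105 of them among the 2315. Without the run term 672 genes were called, all among the 2315, and the counts were 1538 with the f/f controls alone, 1455 with the acinar marker level as a covariate and 1300 on FPKM values with no filter. Leaving out both WT replicates 2 and 5, the libraries with the highest Rn45s shares, gave 1488 genes, 1391 of them shared, and leaving out KO replicate 2 and WT replicate 2, the extremes of acinar marker level in run 1, gave 1519, 1423 of them shared. Both were chosen after the data were seen.

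Genes of endoplasmic reticulum (ER) protein folding and of the integrated stress response were lower in KO islets. Of 26 tested members of the list of ER chaperones and ER-associated degradation, 22 fell, 0 rose and 4 were not called, with the same 22 adjusted over the list alone. The list's median log2 fold change was −0.44 (−0.52 within run 1, −0.43 within run 3), and camera gave an adjusted p of 2.48e-10, against an adjusted p = 0.525 with an estimated correlation. Edem1, which marks misfolded glycoproteins for degradation, fell by 1.19 on the log2 scale (adjusted p = 6.06e-06). Dnajb9, a co-chaperone of the ER lumen, fell by 0.93, Derl1, a component of the retrotranslocation channel, fell by 0.80, and Sel1l, an adaptor of the ER ubiquitin ligase, fell by 0.68. Hspa5, the main ER chaperone BiP, went from 2365 ± 761 CPM (SD, n = 5) to 1444 ± 225 CPM (SD, n = 4), a log2 fold change of −0.62 ± 0.13 (SE) with an adjusted p of 0.00422. Of 27 tested members of the integrated stress response list, 18 fell, 0 rose and 9 were not called, and 23 fell adjusted over the list alone. Its median was −0.50 (−0.62 within run 1, −0.48 within run 3), with a camera adjusted p of 1.77e-11 and an adjusted p = 0.512 with an estimated correlation. Atf4, the transcription factor translated when eIF2alpha is phosphorylated, fell by 0.73, and its targets Trib3, a pseudokinase, and Aldh1l2, a mitochondrial folate enzyme, fell by 1.39 and fell by 1.30. Ddit3, the transcription factor CHOP, went from 345 ± 208 CPM (SD, n = 5) to 109 ± 42.3 CPM (SD, n = 4), with a log2 fold change of −1.49 ± 0.21 (SE) and an adjusted p of 0.000184. Nupr1, a stress-induced chromatin protein, fell by 1.41 (adjusted p = 0.009). The markers of acinar cells, which make digestive enzymes and have abundant ER, had a median log2 fold change of −1.83 within run 1 and of 0.22 within run 3.

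**Figure D2:**
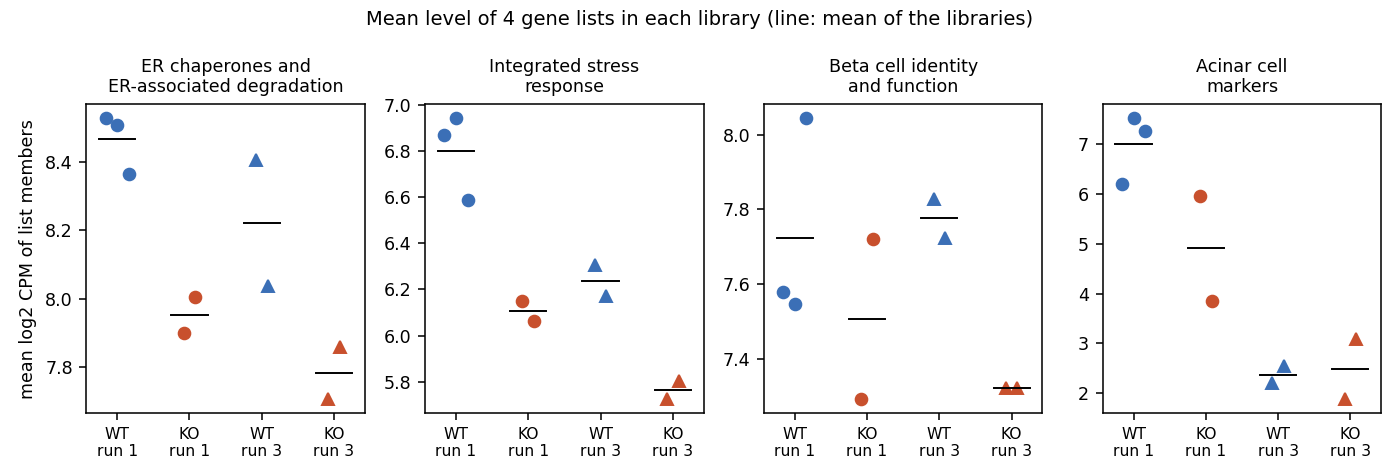
Mean log2 CPM of the members of 4 gene lists in each library, by genotype and run (circles run 1, triangles run 3, blue WT, red KO), with a line at the mean of each set of libraries and a separate vertical scale in each panel that does not start at 0. The ER and stress lists lie lower in every KO library than in every WT library of its run, while the acinar list differs mainly between runs.

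Beta cell genes moved apart, with more falls than rises. Of 28 tested beta cell identity and function genes, 12 fell, 1 rose and 15 were not called, and 13 fell and 1 rose adjusted over the list alone. The median was −0.32 (−0.25 within run 1, −0.41 within run 3), with a camera adjusted p of 0.00158 and an adjusted p = 0.805 with an estimated correlation. The list was called by camera within run 3 (adjusted p = 7.46e-06) and not within run 1 (adjusted p = 0.0986), both with the preset correlation. Its mean log2 CPM difference was −0.218 (95% interval −0.745 to 0.309) in run 1 and −0.454 (−1.03 to 0.123) in run 3, and these differed by −0.236 (−1.02 to 0.546). Over both runs it was −0.325 (−0.684 to 0.0328), and fry did not call the list (adjusted p = 0.137). Abcc8, the sulfonylurea receptor subunit of the ATP-sensitive potassium channel, went from 866 ± 184 CPM (SD, n = 5) to 438 ± 124 CPM (SD, n = 4), with a log2 fold change of −0.93 ± 0.08 (SE) and an adjusted p of 3.1e-06. Kcnj11, the pore subunit of that channel and its neighbour on chromosome 7, fell by 0.65. Ucn3, a peptide that marks mature beta cells, fell from 254 to 101 CPM (log2 fold change −1.30), and Iapp, the co-secreted amyloid peptide, fell by 0.61, a call lost on FPKM values (−0.62). Mafa, a transcription factor of the insulin gene, fell by 1.53 (adjusted p = 0.00152). Its log2 fold change was −0.94 within run 1 (adjusted p = 0.133) and −2.23 within run 3 (adjusted p = 1.43e-06). Nkx6-1, a beta cell transcription factor, fell by 0.29 (adjusted p = 0.0269), a call lost without WT replicates 2 or 4 (−0.27 and −0.28) or KO replicates 1 or 3 (−0.23 and −0.27). It was also lost without the run term, with the f/f controls alone, on FPKM values, with the acinar covariate and without both KO replicate 2 and WT replicate 2. The insulin genes Ins1 and Ins2, whose similar sequences can share reads, were not called, with log2 fold changes of 0.19 ± 0.27 (SE) and −0.16 ± 0.16 (SE), although Ins1 was called without WT replicate 3 (0.56) and stood at −0.06 without KO replicate 2. Neither were Pdx1 (0.13 ± 0.18), a master transcription factor of the pancreas, and Slc2a2 (−0.09 ± 0.20), the glucose transporter GLUT2. With single libraries left out, Ins2 lay between −0.30 and −0.0035, Pdx1 between −0.09 and 0.26 and Slc2a2 between −0.43 and 0.11. Of the 14 tested genes normally held low in beta cells, 0 were called and 0 adjusted over the list alone (camera adjusted p = 0.432). The lowest p-values in it were those of Slc16a1, a lactate transporter, at 1.17 (adjusted p = 0.0584) and Pdgfra, a growth factor receptor, at 0.72 (adjusted p = 0.306). Slc16a1 stood at 0.77 without WT replicate 5, and Pdgfra at 0.19 without KO replicate 1 and at 0.33 with the f/f controls alone. Of 6 tested progenitor and dedifferentiation genes, 1 fell, also adjusted over the list alone, and it was the transcription factor Myc (−0.88, adjusted p = 0.00693), with a camera adjusted p of 0.608. The median of that list was nevertheless 0.26, and its mean log2 CPM difference was 0.231 (95% interval −0.0105 to 0.474).

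Among markers of delta and PP cells 3 were called higher in KO islets, and those of alpha cells gave 1 call. With all libraries, the hormones somatostatin and pancreatic polypeptide passed the threshold only when adjusted over the list alone. Of 9 tested delta, PP and epsilon cell markers, 3 rose, 0 fell and 6 were not called, and 7 rose adjusted over the list alone. Their median was 0.54 (0.78 within run 1, 0.30 within run 3), with a camera adjusted p of 0.00424 and an adjusted p = 0.512 with an estimated correlation. Rbp4, a retinol carrier found in delta cells, rose from 109 to 271 CPM (log2 fold change 1.31, adjusted p = 8.28e-06), and Pyy, peptide YY, rose by 0.80. Etv1, a transcription factor, rose by 0.47, a call lost without KO replicate 1 (0.33) or KO replicate 2 (0.44), with the f/f controls alone (0.32), with the acinar covariate (0.34), without both WT replicates 2 and 5 (0.47) and without both KO replicate 2 and WT replicate 2 (0.41). Somatostatin (Sst, 0.38 ± 0.15 SE, adjusted p = 0.0889) and pancreatic polypeptide (Ppy, 0.54 ± 0.20 SE, adjusted p = 0.0772) were not called over all tested genes with all libraries. Both were among the 7 rises adjusted over the list alone. Sst was called without KO replicate 2 (0.55) and stood at 0.13 without KO replicate 1, and Ppy was called without KO replicate 1 (0.77) and stood at 0.15 without KO replicate 2. Of 10 tested alpha cell markers, 1 rose, 0 fell and 9 were not called, and 2 rose adjusted over the list alone (camera adjusted p = 0.328). Their median was 0.51 within run 1, where camera called the list (adjusted p = 0.0105), and −0.22 within run 3, where it did not (adjusted p = 0.320), both with the preset correlation. The mean log2 CPM difference of the list was 0.527 (95% interval 0.00121 to 1.05) in run 1 and −0.183 (−0.759 to 0.392) in run 3, and these differed by −0.710 (−1.49 to 0.0695). With an estimated correlation the list had an adjusted p = 0.805 over both runs. Glucagon (Gcg, 0.27 ± 0.17 SE, adjusted p = 0.30) was not called and stood at −0.03 without KO replicate 1.

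Genes of calcium handling and signalling changed in both directions. Atp2a2, the SERCA2 pump that fills the ER with calcium, fell from 2753 ± 557 CPM (SD, n = 5) to 1261 ± 249 CPM (SD, n = 4), with a log2 fold change of −1.06 ± 0.09 (SE) and an adjusted p of 3.38e-06. Atp2b4, a plasma membrane calcium pump, rose by 1.22, and Cacna1a, the pore of the P/Q-type calcium channel, rose by 0.59. Of 27 tested calcium channel, pump and store genes, 6 rose, 1 fell and 20 were not called, with 7 rises and 2 falls adjusted over the list alone and a camera adjusted p of 0.328. Of 25 tested genes of secretory granules and exocytosis, 4 rose, 6 fell and 15 were not called, with the same 4 and 6 adjusted over the list alone and a camera adjusted p of 0.432. Among them Sytl4, the granule protein granuphilin, fell by 0.94, and Snap25, a SNARE protein, rose by 0.40. Of 22 tested genes of the insulin, Akt and mTOR pathway, 2 rose, 5 fell and 15 were not called, also adjusted over the list alone, with a camera adjusted p of 0.259. Igf1r, the insulin-like growth factor receptor, fell by 1.10 (adjusted p = 3.94e-06), and Tsc1, an inhibitor of mTORC1, rose by 0.35. The call of Tsc1 was lost without the run term (0.35), with the f/f controls alone (0.29), with the acinar covariate (0.28) and without both KO replicate 2 and WT replicate 2 (0.32). The kinase Gsk3b fell by 0.32, a call lost without KO replicates 1 or 4 or WT replicate 4 (each −0.28).

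**Figure D3:**
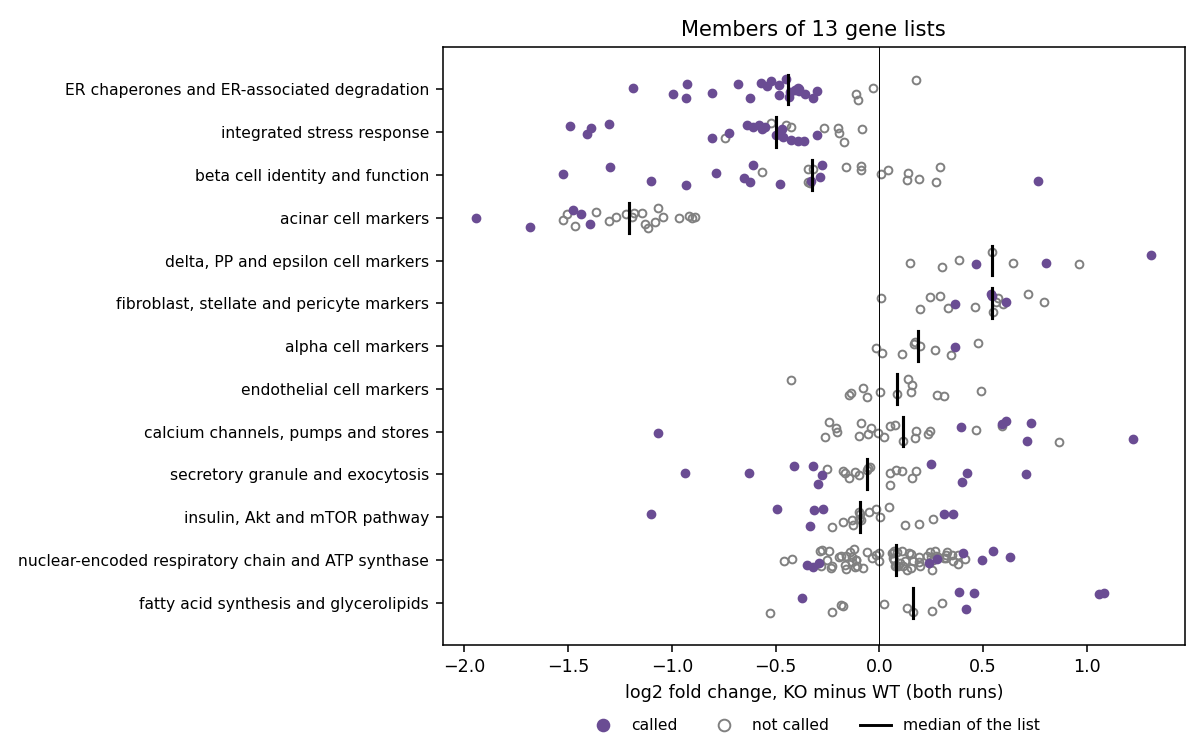
Log2 fold change (KO minus WT, both runs) of the tested members of 13 gene lists, with filled points for called genes, open points for genes not called and a bar at each list's median. The ER list has 22 called falls and 0 called rises, and the beta cell list has 12 falls and 1 rise.

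Each metabolic list held both called rises and called falls. Of 75 tested genes of the nuclear-encoded respiratory chain and ATP synthase, 6 rose, 3 fell and 66 were not called, with 5 rises and 1 fall adjusted over the list alone and a camera adjusted p of 0.473. Camera called this list within run 3 (median 0.13, adjusted p = 0.0419) and not within run 1 (median −0.01, adjusted p = 0.602), both with the preset correlation. The intervals of its mean log2 CPM difference in run 3 (0.132, 95% interval −0.134 to 0.399) and of the difference between runs (0.135, −0.225 to 0.496) took in 0. Ndufa9 of complex I rose by 0.63, and Cox4i1 of complex IV rose by 0.49. Of 20 tested genes of the tricarboxylic acid cycle and pyruvate entry, 4 rose, 5 fell and 11 were not called, with the same 4 and 5 adjusted over the list alone (camera adjusted p = 0.572). The isocitrate dehydrogenase subunit Idh3b rose by 0.75 (adjusted p = 0.000125), while fumarase (Fh1) fell by 0.77 and the pyruvate dehydrogenase subunit Pdha1 fell by 0.51. Of 19 tested mitochondrial biogenesis and dynamics genes, 3 rose and 3 fell, with 4 and 3 adjusted over the list alone and a camera adjusted p of 0.608. Of the mitofusins, which fuse the outer membrane, Mfn2 rose by 0.41 and Mfn1 fell by 0.40 (adjusted p = 0.0146), and the transcription factor Nrf1 fell by 0.42. The call of Mfn1 was lost without KO replicate 3 (−0.33), with the acinar covariate (−0.35), without both WT replicates 2 and 5 (−0.40) and without both KO replicate 2 and WT replicate 2 (−0.37). Of 14 tested glycolysis genes, 1 rose, 2 fell and 11 were not called, also adjusted over the list alone, with a camera adjusted p of 0.409. Aldolase A (Aldoa) fell by 0.71 and pyruvate kinase (Pkm) fell by 0.48, a call lost with the acinar covariate (−0.38). The rise was that of Gapdh, the enzyme after aldolase, which stood at only 4.91 CPM in WT and 17.8 CPM in KO. Its value is uncertain, since it has many related sequences in the genome, went in opposite directions in the runs (−1.85 and 1.71) and lost its call without KO replicate 3 (1.24) or KO replicate 4 (0.98). The Gapdh call was also lost with DESeq2 and on FPKM values. Of 15 tested fatty acid synthesis and glycerolipid genes, 5 rose, 1 fell and 9 were not called, also adjusted over the list alone (camera adjusted p = 0.328). This list was called higher by fry (adjusted p = 0.00694), with a mean log2 CPM difference of 0.184 (95% interval 0.107 to 0.262). Stearoyl-CoA desaturase (Scd1) rose by 1.06 and fatty acid synthase (Fasn) by 0.42, a call lost without both WT replicates 2 and 5 (0.35). Of 18 tested fatty acid oxidation genes, 3 rose, 1 fell and 14 were not called, also adjusted over the list alone (camera adjusted p = 0.328). The mitochondrial uncoupling protein Ucp2 rose from 177 to 312 CPM (log2 fold change 0.84, adjusted p = 5e-06) and the carnitine palmitoyltransferase Cpt1a rose by 0.47, a call lost with the f/f controls alone (0.32). The transcription factor Ppara rose by 1.34, a call lost without KO replicate 1 (1.19). Of 22 tested cholesterol synthesis genes, 1 rose, 2 fell and 19 were not called, also adjusted over the list alone (camera adjusted p = 0.328). Squalene epoxidase (Sqle) fell by 0.63 and lanosterol demethylase (Cyp51) fell by 0.60. The 13 mitochondrially encoded genes were not found in the count table under the names searched.

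A minority of the markers of acinar cells, the source of digestive enzymes, fell, and a minority of those of fibroblasts and pericytes rose, in KO islets, and the acinar markers had a median of −1.83 within run 1 and of 0.22 within run 3. Of 24 tested acinar cell markers, 5 fell, 0 rose and 19 were not called, and 10 fell adjusted over the list alone. Their median was −1.21, with a camera adjusted p of 0.000658 and an adjusted p = 0.805 with an estimated correlation. The mean log2 CPM of the list differed by −2.09 (95% interval −4.19 to 0.0159) in run 1 and by 0.117 (−2.19 to 2.42) in run 3. The mean acinar marker level of the libraries was 6.20, 7.53 and 7.27 log2 CPM in the WT and 5.97 and 3.86 in the KO libraries of run 1, against 2.21 and 2.54 in the WT and 1.88 and 3.10 in the KO libraries of run 3. Without KO replicate 2 the list was not called (median −0.55, adjusted p = 0.179), nor were the digestive enzyme genes Ctrl (−1.03), Rnase1 (−0.92), Cpb1 (−0.98) and the granule lectin Zg16 (−1.54). With all libraries these genes had log2 fold changes of −1.68, −1.39, −1.47 and −1.94. Even with all libraries kept, Ctrl, Rnase1 and Cpb1 lost their calls with DESeq2 and on FPKM values, and Zg16 on FPKM values. Cpb1 also lost its call without WT replicates 2 or 3 (−1.39 and −1.07) or KO replicates 1 or 3 (−1.66 and −1.42), and Zg16 without WT replicates 2 or 3 (−1.89 and −1.52). Of 16 tested fibroblast, stellate and pericyte markers, 4 rose, 0 fell and 12 were not called, and 7 rose adjusted over the list alone. Their median was 0.54 (0.62 within run 1, 0.35 within run 3), with a camera adjusted p of 0.00424 and an adjusted p = 0.525 with an estimated correlation. The pericyte receptor Pdgfrb rose by 0.54 (adjusted p = 0.00639). The collagen VI chains Col6a1 and Col6a3 rose by 0.54 and 0.61 and fibronectin (Fn1) by 0.36. The call of Col6a1 was lost without WT replicate 4 (0.44) or KO replicate 4 (0.48), and that of Col6a3 without KO replicates 1, 2 or 3 (0.57, 0.51 and 0.59) or WT replicate 4 (0.57). That of Fn1 was lost without WT replicates 1, 2, 4 or 5 (0.32, 0.37, 0.28 and 0.41) or KO replicates 1, 2 or 3 (0.41, 0.35 and 0.27). With the f/f controls alone the calls of Col6a1, Col6a3 and Fn1 were lost. Those of Col6a3 and Fn1 were also lost with the acinar covariate and on FPKM values. Fn1 lost its call with DESeq2 and with RLE size factors too.

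Markers of the remaining cell types gave 0 to 2 calls per list, where 2315 of all 12501 tested genes were called. Of 7 tested duct cell markers, 1 rose and 6 were not called, with 1 rise and 1 fall adjusted over the list alone and a camera adjusted p of 0.728. The duct list had a median of −0.23 and a mean of 0.05. The rise was that of Ambp, the precursor of alpha-1-microglobulin and bikunin, from 12.8 ± 2.23 CPM (SD, n = 5) to 49.1 ± 11.8 CPM (SD, n = 4), a log2 fold change of 1.93 with an adjusted p of 3.1e-06. Of 13 tested endothelial markers, 0 were called by edgeR and 0 adjusted over the list alone, and camera placed the list slightly down with an adjusted p of 0.998 although its median was 0.08. The list's median was 0.43 within run 1 (camera adjusted p = 0.355) and −0.30 within run 3, where camera with the preset correlation called it lower (adjusted p = 0.0176). The correlation estimated for the list was 0.551, and the interval of its mean log2 CPM difference in run 3 took in 0 (−0.285, 95% interval −1.16 to 0.590), as did that of the difference between runs (−0.617, −1.80 to 0.568). The endothelial genes with the lowest p-values were the adhesion molecule Pecam1 (0.49 ± 0.33 SE, adjusted p = 0.331) and the diaphragm protein Plvap (0.31 ± 0.25 SE, adjusted p = 0.42), which stood at 0.01 and −0.21 without KO replicate 2. Of 18 tested macrophage and antigen-presenting cell markers, 2 rose and 16 were not called, and 1 rose adjusted over the list alone (camera adjusted p = 0.473). The mean log2 CPM effect on this list was 0.376 in run 1 and −0.00464 in run 3, a difference of −0.381 (95% interval −0.620 to −0.142). It was the 1 of 33 lists whose interval left out 0, where chance gives about 1.65, and adjusted for the 33 lists the interval was −0.963 to 0.202. The fractalkine receptor Cx3cr1 rose by 1.06, a call lost without WT replicate 4 (0.92) or KO replicate 4 (0.85). Lysozyme (Lyz2) rose by 0.78, a call lost without WT replicates 1, 3, 4 or 5 (0.80, 0.62, 0.76 and 0.81) or KO replicates 1 or 4 (0.65 and 0.62). The Lyz2 call was also lost with DESeq2, with RLE size factors, with the f/f controls alone and on FPKM values. Of 2 tested T and B cell markers 1 rose, also adjusted over the list alone, and it was the B cell receptor component Cd79a (1.42), with a call lost without KO replicate 2 (0.98) or KO replicate 3 (1.44). Of 6 tested Schwann and glial markers 1 rose, also adjusted over the list alone (camera adjusted p = 0.473). The only adipocyte marker tested, the fatty acid carrier Fabp4, was not called (−0.07 ± 0.45 SE, and −0.40 to 0.37 with single libraries left out), and 0 of 8 red blood cell markers had enough counts to be tested. Of the sex check genes only Xist, the RNA of the inactive X chromosome, was tested. It fell by 0.59 (adjusted p = 0.0452), from 257 ± 242 CPM (SD, n = 5) to 166 ± 88.1 CPM (SD, n = 4), a call lost without WT replicates 2 or 5 (−0.64 and −0.27) or KO replicates 1, 3 or 4 (−0.62, −0.55 and −0.44). The Xist call was also lost with DESeq2 and on FPKM values.

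The KO effect was also measured within each sequencing run. Within run 1, 756 genes were called by edgeR, 391 higher and 365 lower in KO, and within run 3 there were 1021, 491 higher and 530 lower. The calls with the lowest p-values within run 1 included rises of Dlk1 (4.02 on the log2 scale), Sema6a (2.84) and Sumf1 (1.68) and falls of Gsdma (−1.98), Aldh1l2 (−1.57) and Edem1 (−1.37). Within run 3 they included rises of Dlk1 (3.19), Cd44 (1.90) and Sumf1 (1.77) and falls of Ddit3 (−1.31), Mafa (−2.23) and Atp2a2 (−0.96). The runs share no library. They had 396 called genes in common, against 61.7 for independent lists, and 395 of these changed in the same direction, against 30.8. Across genes, which are not independent replicates, the log2 fold changes of the runs correlated with Pearson's r of 0.489 and Spearman's rho of 0.509, and 70.0% of all 12501 tested genes had the same sign in both. Of the genes called within run 1, 96.2% had the same sign in run 3. Of the 2315 genes called over both runs 2310 did, a share that the selection by the pooled test raises. The test of the difference itself, the interaction of genotype and run, called 0 genes with edgeR at an adjusted p under 0.05, with 744 genes at an unadjusted p under 0.05, and DESeq2 also called 0 (377 at an unadjusted p under 0.05). On simulated counts that test recovered 20.9% of interactions of 2-fold and 78.8% of those of 4-fold. Without WT replicate 3, 6 genes were called (Pianp, Mt2, Mt1, Rian, Thbs1 and Star), and without KO replicate 2, WT replicate 5 or KO replicate 3 there was 1 each (Arhgap36, Srp54b and Akap6), all named after their values were seen. With the spread shared over all 9 libraries the counts were 1294 for run 1 and 540 for run 3.

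**Figure D4:**
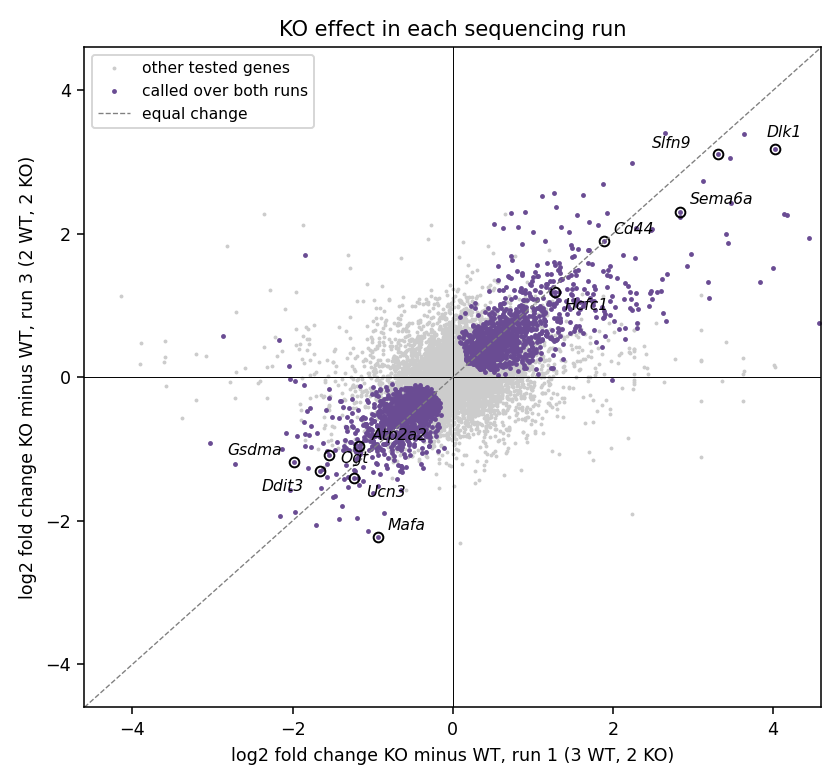
Log2 fold change KO minus WT of each tested gene within run 1 (horizontal axis, 3 WT and 2 KO libraries) and within run 3 (vertical axis, 2 WT and 2 KO libraries), with genes called over both runs in purple, other genes in grey and a dashed line of equal change. Over all tested genes 70.0% have the same sign in both runs, the purple genes were selected by the test over both, and 8 genes lie outside the axis limits of 4.6.

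The runs themselves differed in more genes than the genotypes did. With genotype in the model, edgeR called 3921 genes between runs, 1888 higher and 2033 lower in run 3. The ribosomal protein genes Rps23 and Rpl5 rose by 7.42 and 6.02 on the log2 scale in run 3 and Tpt1, a translationally controlled tumour protein, by 4.57. Rps23 stood at 2.02 to 2.59 CPM in the libraries of run 1 and at 385 to 428 CPM in those of run 3. Such genes have related copies in the genome that can share reads, so their levels are uncertain. Whether the reads of both runs were aligned and counted in the same way is not given in the sources used here, so the values between runs cannot be divided into differences of the libraries and of their processing. The lowest p-values among falls were those of BC002163 (−2.18), Tapbp, a peptide-loading factor of MHC class I (−0.996), and Smarca5-ps, a pseudogene (−2.09). DESeq2, with its own size factors and its own filter, called 6016 genes, 3878 higher and 2138 lower in run 3, so that 64.5% of its calls were higher against 48.2% in edgeR, with the median of all genes shifted by 0.44 on the log2 scale. Run 3 libraries had larger totals and more detected genes than run 1 libraries.

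The controls carried either 1 or 2 floxed Ogt alleles. Ogt itself was 0.54 higher on the log2 scale in the 2 f/+ libraries than in the 3 f/f libraries, with run in the model, and was not called. With edgeR 0 genes were called between f/+ and f/f controls, with 398 at an unadjusted p under 0.05, and DESeq2 called 0 with 237 at an unadjusted p under 0.05. Without WT replicate 1 there were 5 calls, named after their values were seen, but WT replicate 3 was then the only f/+ library, set against 1 f/f library in its run and assumed to vary like the other groups. In that library the glycolytic genes Pfkl (1.70), Tpi1 (1.43) and Pfkp (1.64) and the collagen prolyl hydroxylase P4ha1 (1.28) were higher than in the f/f libraries, and the ribonuclease Rnase4 (−1.53) was lower. The mean log2 CPM of the glycolysis list was 5.86 in WT replicate 3, against 4.95 in WT replicate 1, the other f/+ library, and 4.95 in WT replicate 2, so these calls describe 1 library and not the genotype. Both f/+ libraries were in run 1, where only WT replicate 2 was f/f, and the same test recovered 40.3% of 2-fold changes in simulated counts.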

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

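The tests of explanations below and the counts over other splits of the samples were chosen after the results they address were seen, while the rule for single libraries that stand apart was fixed before. ER chaperone and integrated stress response genes were lower in KO islets. The mean log2 CPM of both lists together differed by −0.54 (95% interval −0.74 to −0.34). The exact within-run permutation p was 0.0167, the smallest possible of 60 arrangements, and 0.0611 for each list after adjustment over 33 lists. These p-values are not particular to the ER and stress lists. The delta and PP, fibroblast, Schwann, fatty acid synthesis, insulin and Akt, lactogen and immediate-early lists reached them too. Less acinar RNA in KO libraries is argued against as the whole cause, since the difference was −0.457 (−0.773 to −0.140) in run 3, where the acinar list was not lower in KO (0.117, −2.19 to 2.42), and −0.513 (−0.778 to −0.248) with the acinar marker level as a covariate. Libraries rich in Rn45s counts are argued against in the same way, since the effect was −0.568 (−0.760 to −0.376) without WT replicates 2 and 5. A lower share of beta cells stays open, because the lists fell by no clearly larger amount than the beta cell list (difference −0.213, −0.704 to 0.279). The Rip-cre transgene itself cannot be told apart from the deletion, since 0 libraries carried it with Ogt intact, and loss of Ogt in beta cells remains a candidate explanation beside these.

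Of the beta cell genes 12 of 28 fell, and 3 of 9 delta, PP and epsilon and 4 of 16 fibroblast markers rose. These lists were not called by camera with an estimated correlation (adjusted p = 0.805, 0.512 and 0.525). The changes of the beta cell genes differed by more than their standard errors (Cochran's Q of 14.2 per degree of freedom), with 1 of them called higher. That statistic takes the genes as independent, while their estimated correlation was 0.396. A lower share of beta cells would lower these genes alike only if beta cells alone expressed them, which was not tested. The unequal changes therefore do not by themselves decide whether a lower share accounts for the pattern. With insulin RNA per beta cell unchanged, a lower share alone would lower the insulin genes at least as much as any other gene. Ins1 (0.19 ± 0.27 SE) and Ins2 (−0.16 ± 0.16 SE) were not called. Abcc8 (−0.93 ± 0.08 SE), Kcnj11 (−0.65 ± 0.10 SE) and Ucn3 (−1.30 ± 0.13 SE) fell. On that condition, which was not tested, the insulin values argue against a lower share as the whole cause of those falls. A lower share of beta cells would also raise the markers of all other cell types alike. Here the delta and PP list stood 0.532 above the endothelial list, with an interval (−0.451 to 1.52, adjusted for 10 pairs) that decides nothing. Less acinar RNA would raise all other RNA alike, but with the acinar marker level as a covariate 10 beta cell genes were called as falls and 1 as a rise, and the effects on the delta and PP list (0.584 without it, 0.522 with it, 0.253 to 0.792) and the fibroblast list (0.503 without and with it, 0.0757 to 0.930) stayed above 0, which argues against it as the whole cause. The mean of the beta cell list decided less. It was −0.325 (−0.684 to 0.0328) without the covariate, with an exact within-run permutation p of 0.10. With the covariate it was −0.430 (−0.859 to −0.00177), and that interval took in 0 when any of 7 single libraries was left out. The fibroblast interval took in 0 without WT replicates 1 or 4 (0.445 and 0.483) or KO replicates 1 or 3 (0.372 and 0.497). A lower share of beta cells, at least as part of the cause, a change of share in part of the cells, the transgene and regulation within beta cells therefore all stay open.

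Single libraries stood apart from the rest of their group in 6 of 270 sets of values examined, where chance gives about 13.5, 4 of them in WT and 2 in KO. The distance is the gap to the nearest library divided by the range of the group. Each group pooled the libraries of both runs, and a difference between runs widens that range. The figure for chance therefore does not hold where the runs differ. In KO, Ins1 was high in KO replicate 2, at 13.6 against 12.8 log2 CPM for the next library (0.854 of the range), and the share of Gcg among counts was high in KO replicate 1, at 5.97% against 3.01% (0.911). In WT replicate 3, Ambp was low at 3.23 against 3.74 log2 CPM (0.768), Pecam1 was high at 5.92 against 4.45 (0.728), and Pkm was high at 9.28 against 8.66 (0.834). In WT replicate 2, Snap25 was low at 6.88 against 7.09 log2 CPM (0.749). The lowest adjusted p for a different KO effect in the runs was 0.795 among the 125 genes examined for the text.

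Other splits of the 9 libraries were compared with the real ones. For KO against WT, 1 of 100 splits, the real one, gave as many genes (2315, against 925 for the highest other). The splits were drawn over both runs, with run but not genotype in the model. A genotype effect therefore adds to the spread in the other splits and lowers their counts, so this comparison cannot exclude chance. The 5 drawn splits that set 4 of the WT libraries against the rest reached up to 925 genes and the other 94 up to 3, which reflects the genotype structure of the samples. For the run term, 1 of 100 splits, the real one, gave as many genes (3921, against 2071), and the other splits likewise leave the run effect in the spread. For the number of gene lists called by camera, 59 of 100 splits gave as many as the real 6, and the highest other gave 13, so chance cannot be excluded for that number.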

How the results depend on the processing

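The alternatives that left out WT replicates 2 and 5, or KO replicate 2 and WT replicate 2, or removed Rn45s and Lars2 were chosen after the data were seen. Ogt was lower in KO and called under all alternatives run for it (log2 fold changes of −1.43 to −1.12). For KO against WT, 2315 genes were called, and leaving out single libraries gave 1595 to 2334. It moved by over 1.5 times without the run term (672), with f/f controls alone (1538), with the acinar covariate (1455), on FPKM without a filter (1300), without WT replicates 2 and 5 (1488) and without KO replicate 2 and WT replicate 2 (1519); fewer libraries were tested in the f/f and left-out settings, and for the others the cause was not tested. Of 113 called genes among those examined for the text, 61 stayed called without the run term. With the spread shared over all 9 libraries the calls went from 756 to 1294 in run 1 and from 1021 to 540 in run 3, and with DESeq2 the calls between runs went from 3921 to 6016 (leaving out single libraries gave 2719 to 4243); the cause was not tested. The interaction gave 0 calls and 0 to 6 with single libraries left out, and the f/+ comparison 0 and 0 to 5, the 5 with a single f/+ library left. Over the 125 genes examined and their alternatives, 1996 of 2239 values kept direction and call, 239 lost the call, 4 gained it and 0 reversed, and 59 of the 113 called genes never lost it. All 66 values of the 6 genes named between runs kept direction and call. Of 561 values for the 33 lists, 555 kept theirs, and the number of called lists lay between 5 and 7. The acinar list was lost without KO replicate 2, without KO replicate 2 and WT replicate 2, or with the acinar covariate, the fibroblast list was lost without the run term, and the O-GlcNAc list was gained without WT replicate 5 or on FPKM. DESeq2 gave no list values, since it tests genes only. In simulated counts at the real depths the interaction test recovered 1.5% of 1.5-fold differences, against 44.8% for KO against WT, and since depth was not varied its own part in that is not known.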

Other observations

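The tests on neighbouring genes below were chosen after the results were seen, and so was Hcfc1, while the gene lists were fixed before. Hcfc1, a transcriptional co-regulator that O-GlcNAc transferase modifies and cleaves, rose from 124 ± 14.1 CPM (SD, n = 5) to 289 ± 45.8 CPM (SD, n = 4) in KO islets, a log2 fold change of 1.25 ± 0.07 (SE) with an adjusted p of 2.32e-08 in edgeR's test. Lysosomal and autophagy genes went both ways, with 3 rises and 5 falls among 22 tested, 4 and 5 adjusted over the list alone, and a camera adjusted p of 0.618. The lysosomal membrane protein Lamp2 fell by 0.61, the proteases cathepsin L (Ctsl) and cathepsin B (Ctsb) fell by 0.61 and fell by 0.54, and the autophagy receptor Sqstm1 fell by 0.55. Of 19 tested SR splicing factor and CLK kinase genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.699). The splicing factors Luc7l and Tra2a rose by 0.51 and 0.68, and Luc7l2 fell by 0.37. Of 10 tested genes of the lactogen response of islets, 1 rose and 3 fell, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.241). The prolactin receptor (Prlr) fell by 0.63 and Igfals, a carrier subunit for insulin-like growth factors, fell by 0.89. The muscle protein gene Neb rose by 0.85, a call lost without KO replicate 1 (0.70), WT replicate 5 (0.84) or KO replicate 3 (0.85).

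Stress and growth lists gave 1 to 4 calls each, where 2315 of all 12501 tested genes were called. Of 28 tested cell cycle genes, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.328). Camera called the list within run 3 (median 0.47, adjusted p = 0.0321) and not within run 1 (median 0.17, adjusted p = 0.497), both with the preset correlation, against an adjusted p = 0.805 with an estimated correlation over both runs. The intervals of its mean log2 CPM difference in run 3 (0.397, 95% interval −0.619 to 1.41) and of the difference between runs (0.154, −1.22 to 1.53) took in 0. The cyclin Ccnd2, the main D-type cyclin of beta cells, fell by 0.39. The replication helicase subunit Mcm3 rose by 0.78, a call lost without KO replicates 2 or 3 (0.73 and 0.74) or WT replicates 4 or 5 (0.78 and 0.76). Of 21 tested p53 target and apoptosis genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.645), among them the RNA-binding protein Zmat3, which rose by 0.43. Cyclin G1 (Ccng1) fell by 0.48, a call lost without KO replicate 2 (−0.41) or KO replicate 3 (−0.46). Of 20 tested antioxidant genes, 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.648). The glutathione synthesis enzyme Gclc rose by 0.59, and the peroxiredoxin Prdx5 rose by 0.48, a call lost without KO replicate 1 (0.38). The lipid peroxidase Gpx4 fell by 0.50, a call lost without WT replicates 1, 2, 4 or 5 (−0.49, −0.45, −0.45 and −0.54) or KO replicates 1 or 3 (−0.43 and −0.40). The Gpx4 call was also lost with DESeq2, on FPKM values and with the acinar covariate. Of 17 tested interferon response genes, 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.648). The RNA sensor Ifih1 rose by 0.65, a call lost without both WT replicates 2 and 5 (0.42), and Ifit1 rose by 0.85, a call lost without WT replicate 2 (0.77) or KO replicates 1 or 3 (0.62 and 0.89). Of 10 tested NF-kB and cytokine genes, 1 fell, also adjusted over the list alone (camera adjusted p = 0.661), and it was the interleukin-1 receptor Il1r1, which fell by 0.43. Of 14 tested immediate-early genes 1 rose, and 0 were called adjusted over the list alone (camera adjusted p = 0.328). It was Egr1 (0.66), a call lost without WT replicates 2, 3 or 5 (0.67, 0.50 and 0.67) or KO replicates 1, 2 or 4 (0.56, 0.62 and 0.68). The immediate-early list was called higher by fry (adjusted p = 0.0194), with a mean log2 CPM difference of 0.175 (95% interval 0.0643 to 0.286).

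Neighbouring genes tended to change together. Of 12031 adjacent pairs of tested genes, 260 were called in the same direction, against a mean of 211 and a highest value of 255 when genes were shuffled within chromosomes (permutation p = 1e-04, the smallest that 10000 shuffles can give). Without pairs that overlap or share the letters of their symbol there were 232, against a mean of 184 and a highest value of 229 (permutation p = 1e-04, again the smallest possible), so reads shared by related neighbours are argued against as the whole cause. Regulation over regions of chromosomes may contribute, a hypothesis for which no further test was run.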
